A study of Mus musculus with 4 samples.

How the data were processed

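The samples were cultures of JoMa1.3, a conditionally immortalised mouse neural crest cell line, transfected with a pool of siRNAs against Stk11, the mouse gene that encodes the kinase LKB1, or with a pool of non-targeting siRNAs. Per the labels' protocols, the siRNA concentration was 60 nM, RNA was taken 72 h after transfection, and libraries were sequenced as read pairs of 150 bp. The labels name 2 transfection reagents without saying which sample received which. Each group held 2 libraries, and the labels give each library a culture number and a batch, so that batch 1 and batch 2 each held 1 library of either group.

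Per the submitters' processing notes, the authors used HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.8 with the mouse build GRCm39; the notes give no role or order for these tools, and the annotation release was not given in the sources used here. Per the file headers, the deposited gene table held for each library a read count, a normalised read count and an FPKM. The read counts were expected counts, which the authors made by estimating how many fragments came from each gene or transcript before depositing them, as their values show: between 5.7 and 6.0% of the gene counts in a library were not whole numbers. The deposited normalised read count was a signal made by the authors from the read count, raised to the next whole number and multiplied by 1 factor per library, between 0.953 and 1.05; it was checked against the counts and entered no test. The FPKM was the authors' deposited value, relative to transcript length and library size. The gene table listed 15768 genes by NCBI gene ID and symbol, of which 15562 were protein coding in the RefSeq gene table (GRCm38) used for names, and the transcript table listed 53915 RefSeq transcripts. In 14 cells of the gene table and 20 cells of the transcript table the decimal point was doubled; these were read with 1 point, after which the deposited group means matched the means of the libraries within 0.001 in every row. A pair of symbols that had been turned into dates was restored through the gene ID.

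The gene counts summed to between 17426719 and 19324675 per library. Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test with robust estimation and TMM normalisation, after the tool's expression filter (minimum count 10), which left 12222 genes. The log2 fold change was Lkb1 siRNA minus control siRNA, its standard error (SE) was derived from the F statistic, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values are given as mean ± SD of the 2 libraries of a group. The transcript counts were tested in the same way, without a correction for the uncertainty of assigning reads to transcripts. The labels do not say whether the cultures were independent beyond their number and batch. The p-values of the main gene tests therefore measure the spread between these libraries, with weight given to the spread of other genes.

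A total of 38 gene lists were fixed before the data were examined, covering neural crest cells and their derivatives, LKB1 signalling, metabolism, stress responses, the cell cycle and other cell types. They named 898 genes, 795 of which were in the gene table, and 34 lists had at least 5 tested members. Lists were tested with camera in limma 3.58.1 (inter-gene correlation 0.01, adjusted over the lists), and also with an estimated correlation, with fry and with cameraPR. Camera with the preset correlation, and cameraPR, set the members against the other genes, so their p-values measure mainly the spread among genes. Members passing over all genes tested were counted beside members passing when adjusted over the list alone. The genes named in the text were set by a rule fixed at the same time: Stk11; up to 12 genes with the largest change in each direction among genes passing the threshold, with a mean of at least 2 CPM and the same sign in both batches, or the 5 with the smallest p where fewer than 5 passed in a direction, skipping predicted genes; and up to 4 members with the smallest p of each list described. The gene families of the closing section and their members, and Penk, Atf4, Cdkn1a, Mdm2, Wrap53 and Ddi2, fall outside that rule and were chosen after the values were seen.

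The labels state that the culture number marks a shared batch, so the numbers pair the libraries. The fit without the block was fixed as the main test, and the fit with batch as a replicate block was fixed beside it. The check of the pairing gave a correlation of 0.259 between the deviations of same-batch libraries from their group means across the 12222 genes, and a principal component analysis of log2 CPM put the groups apart on the component with 42.5% of the variance and the batches apart on the component with 37.7%. With the replicate block, 1579 genes differed between the batches, and the common biological coefficient of variation was 3.15% against 6.39% without it. The blocked fit has 1 residual degree of freedom per gene. The weight given to the other genes (prior degrees of freedom) had an infinite median with the block, against 7.27 without it. At that median a gene's spread came wholly from the other genes, so the blocked p-values rest on a pooled spread. Libraries of the same group were not copies of each other: the chi-square of their counts per degree of freedom was 7.77 for the control siRNA libraries and 4.8 for the Lkb1 siRNA libraries.

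The tests were checked on simulated data drawn from the real means and library sizes with 200 genes changed by known folds, 50 at each fold, and 12139 and 12148 genes tested. Without simulated batch differences, the main test recovered 10 of 50 genes changed 1.25-fold, 40 of 50 changed 1.5-fold, 47 of 50 changed 2-fold and 50 of 50 changed 4-fold. With batch differences as large as the measured ones, it recovered 0, 28, 41 and 49 of 50 genes at these folds, and the blocked fit recovered 33, 46, 50 and 50, with 11 unchanged genes called. The simulated spread followed a trend with expression level only, without further differences between genes. The blocked fit makes nearly that assumption, so the simulation cannot tell how many of its calls in the measured data are false. A planted list of 25 genes shifted by -0.3 on the log2 scale was called by camera with the preset correlation (adjusted p = 5.4e-11 in the blocked fit with batch differences), but not with the estimated correlation (adjusted p = 0.976) or by fry (adjusted p = 0.0753), so these last tests could miss a shift of that size here. The simulated genes were independent, so this does not show that the preset correlation of 0.01 suits the measured lists. With an estimated correlation, camera uses the residual degrees of freedom, 2 in the main fit and 1 in the blocked fit. On so few, hardly any list could pass, so a list failing this test is not evidence against it. Among the 11 lists called below, the estimated correlation in the main fit ran from -0.057 (smooth muscle) to 0.816 (interferon), and was 0.217 for the ATF4 list.

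The alternatives, recomputed for each gene named by the rule and each of the 34 lists where they apply, were the block, DESeq2 1.42.0 with and without the block, RLE factors or library size in place of TMM, a filter of at least 1 count in any library or of at least 5 CPM in 2 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, non-robust estimation, a fold-change threshold of 1.2 (for the counts of genes only), and leaving out each library in turn. The effect of gene length was examined with the length implied by count and FPKM, and 3′ UTR sequences of the GENCODE mouse annotation (release M21, build GRCm38) were searched for short words in Python 3.11.15 with numpy 2.4.6. Because that build differs from the authors', no coordinates are given. Sox10, Ret and the mitochondrially encoded genes were not analysed here.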

Results

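The data were RNA-seq libraries of JoMa1.3 cells, a mouse neural crest cell line, 72 h after transfection with control siRNA or with siRNA against Lkb1 (Stk11), with 2 libraries in each group. The study asked which genes act downstream of a loss of Lkb1 in these progenitors. The gene counts summed to 18718435 and 19324675 in the control siRNA libraries and to 17426719 and 18496820 in the Lkb1 siRNA libraries, in the order of batch 1 and batch 2.

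Stk11 (gene ID 20869), the siRNA target, encodes LKB1, a kinase that activates AMPK and its relatives. Its level was 52.7 and 52.1 FPKM in the control siRNA libraries and 36.3 and 36.9 FPKM in the Lkb1 siRNA libraries. In counts it went from 119.7 ± 2.57 to 81.7 ± 0.433 CPM (SD, n = 2 per group), a change of -31.7% with a 95% confidence interval from -38.4 to -24.3%. Stk11 fell by 0.55 on the log2 scale (SE 0.0659, adjusted p = 0.0378, edgeR's quasi-likelihood test), by 0.58 in batch 1 and by 0.52 in batch 2. Both libraries of each group therefore lay on the side their labels give. The adjusted p was over the threshold with library size in place of TMM (0.0633), with a minimum of 5 CPM (0.0502) and with limma on log2(FPKM + 1) (0.114) or log2(FPKM + 0.1) (0.122).

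After Lkb1 siRNA, 4 genes rose and 6 fell. The genes that rose were Trp53 (gene ID 22059), which encodes the tumour suppressor p53, Mat2a (232087), an S-adenosylmethionine synthetase, Adamts17 (233332), a secreted metalloprotease, and Rsc1a1 (69994). Trp53 went from 30.9 ± 0.291 to 51.4 ± 0.66 CPM, a log2 fold change of 0.74 (SE 0.0782, edgeR adjusted p = 0.026). Mat2a went from 113.7 ± 5.59 to 175.8 ± 3.37 CPM (log2 fold change 0.63, SE 0.0691, edgeR adjusted p = 0.026), and Adamts17 from 73.2 ± 0.654 to 115.7 ± 12.9 CPM (log2 fold change 0.66, SE 0.0849, edgeR adjusted p = 0.0378). Rsc1a1 had the largest fold, 3.59, at 1.605 ± 0.509 against 5.75 ± 0.0848 CPM (edgeR adjusted p = 0.0458). It lies within Ddi2 in the RefSeq gene table (GRCm38), so its reads are uncertain, and Ddi2 itself was at 33.2 against 31.9 CPM (edgeR adjusted p = 0.875). Reep1 (52250), a shaper of the endoplasmic reticulum, had the fifth smallest p among higher genes and did not pass, at 7.84 ± 0.355 against 15.4 ± 2.13 CPM (edgeR adjusted p = 0.07; 7.91e-14 with the replicate block).

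Besides Stk11, the genes that fell were Trib3 (228775), a pseudokinase induced by amino acid shortage, Atf5 (107503), a stress-induced transcription factor, Aldh1l2 (216188), a mitochondrial enzyme of folate metabolism, Stbd1 (52331), a glycogen-binding protein, and Anxa3 (11745), an annexin. Trib3 had the largest decrease, from 39.9 ± 1.22 to 18.7 ± 2.58 CPM, a log2 fold change of -1.095 (SE 0.109, edgeR adjusted p = 0.026). Stbd1 went from 19.5 ± 1.44 to 10.7 ± 0.0637 CPM (edgeR adjusted p = 0.046) and Aldh1l2 from 82.5 ± 2.35 to 51.5 ± 6.08 CPM (edgeR adjusted p = 0.0378). Atf5 went from 59.3 ± 3.64 to 38.5 ± 0.208 CPM and Anxa3 from 76.5 ± 1.95 to 51.1 ± 2.01 CPM, both with an edgeR adjusted p of 0.0378. All 10 genes moved the same way in both batches. With library size in place of TMM, or with a minimum of 5 CPM, Trp53, Mat2a and Trib3 passed and the other 7 did not. With limma on FPKM, or with a test against a fold change of 1.2 in edgeR, none of the 10 passed, and Stbd1 did not pass when the trend with gene length was removed (edgeR adjusted p = 0.0539).

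**Figure D1:**
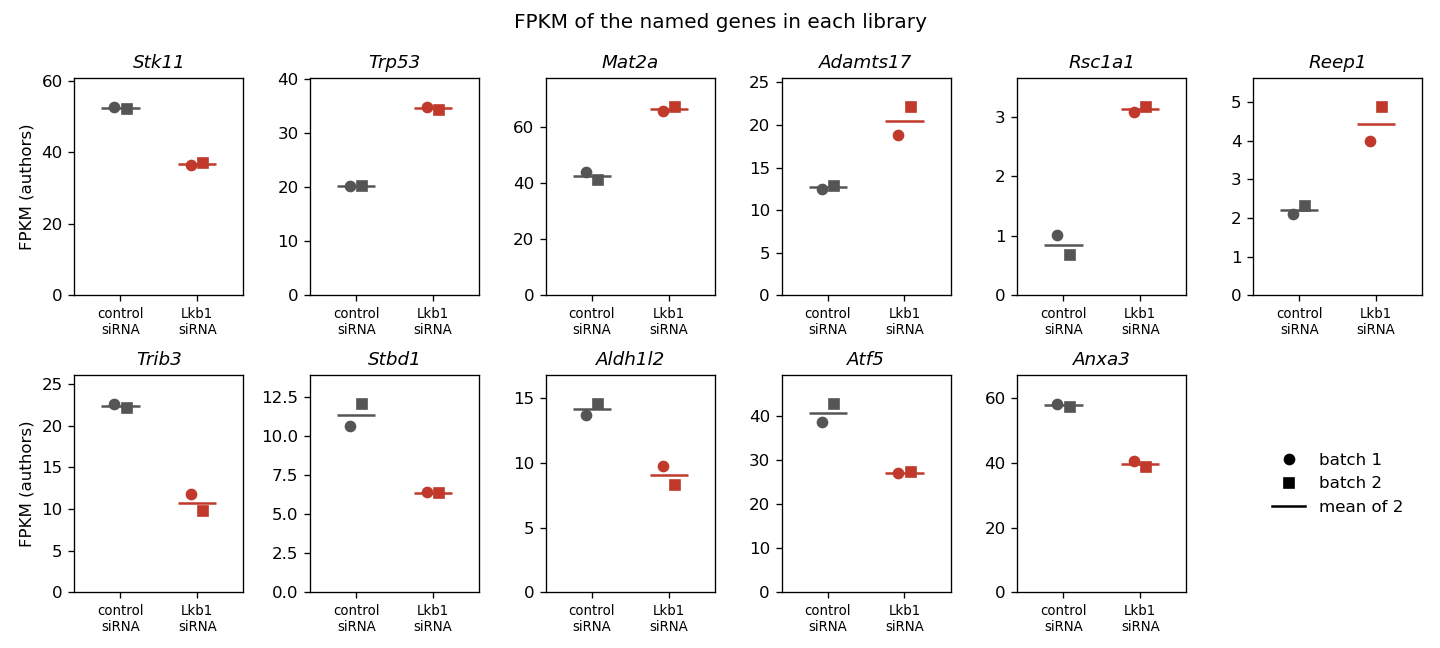
The authors' FPKM (vertical axes, each starting at 0) of Stk11 and the 10 other genes set by the naming rule in each of the 4 libraries; circles are batch 1, squares batch 2, and bars the mean of the 2 libraries of a group. Stk11 lies at 52.7 and 52.1 FPKM after control siRNA and at 36.3 and 36.9 FPKM after Lkb1 siRNA, and for each gene plotted the libraries of the groups do not overlap.

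The number of genes passing depended on the fit. With batch as a replicate block, 806 genes passed as higher and 854 as lower, the 10 genes above among them. Of these 1660 genes 1654 had the same sign in both batches, against 67.2% of all genes tested. The blocked fit favours genes whose changes in the 2 batches agree, so this count is no support for its calls. At an unadjusted p under 0.05 the main test gave 686 higher and 676 lower genes. DESeq2 called 16 and 31 without the block and 44 and 80 with it, where some genes tested by edgeR received no adjusted p. Limma on FPKM and edgeR's test against a fold change of 1.2 called none. Leaving out a library moved the counts to 110 higher and 143 lower (without control siRNA replicate 1), 136 and 88 (without control siRNA replicate 2), 54 and 43 (without Lkb1 siRNA replicate 1) or 24 and 42 (without Lkb1 siRNA replicate 2). Scaled by library size alone, 2 genes were higher and 1 lower.

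Of the 34 gene lists tested, 11 were lower and none higher after Lkb1 siRNA by camera. At an unadjusted p under 0.05, 1 list was higher by camera. With an estimated correlation, and with fry, no list passed in either direction, while cameraPR called 0 lists as higher and 11 as lower. The estimated correlation is tested on 2 residual degrees of freedom, or 1 with the block, which hardly any list could pass. Both tests also missed the planted shift of -0.3. Failing them therefore does not decide for or against the 11 calls. The list of ATF4 and amino acid response genes had the smallest p and fell. ATF4 is the transcription factor that cells activate when amino acids run short or protein folding fails, and its targets include enzymes of serine, asparagine and proline synthesis. All 33 measured members had a lower mean after Lkb1 siRNA, 30 of them in both batches, with a median log2 fold change of -0.315 (camera adjusted p = 4.01e-32; adjusted p = 0.632 with an estimated correlation). Of these, 3 passed over all genes (Trib3, Atf5 and Aldh1l2), 21 when adjusted over the list alone and 25 in the fit with the replicate block. Chac1, a glutathione-degrading enzyme, was at 24.7 ± 0.257 against 15.3 ± 1.91 CPM and did not pass (edgeR adjusted p = 0.0847; 1.08e-11 with the replicate block).

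The lists of lipid synthesis genes fell as well. All 24 measured cholesterol biosynthesis genes were lower, 23 of them in both batches, with a median log2 fold change of -0.17 (camera adjusted p = 1.25e-13; adjusted p = 0.632 with an estimated correlation). No member passed over all genes, 8 passed adjusted over the list alone and 14 with the replicate block. The smallest p belonged to Mvd, mevalonate diphosphate decarboxylase (log2 fold change -0.55, SE 0.0881), Fdps, farnesyl diphosphate synthase (-0.46, SE 0.0751), Nsdhl (-0.37, SE 0.0695) and Msmo1 (-0.27, SE 0.0652), with edgeR adjusted p from 0.0844 to 0.196 and, with the replicate block, from 3.5e-18 to 5.53e-06. Of 17 fatty acid synthesis genes 15 were lower, with a median of -0.145 (camera adjusted p = 1.64e-05; adjusted p = 0.632 with an estimated correlation). None passed over all genes, 5 adjusted over the list alone and 9 with the replicate block. Among them the stearoyl-CoA desaturases Scd1 and Scd2 had log2 fold changes of -0.26 (SE 0.0632) and -0.22 (SE 0.0614), with edgeR adjusted p of 0.196 and 0.26 (3.51e-06 and 5.67e-06 with the replicate block).

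Lists of energy metabolism fell too. Of 19 glycolysis genes 16 were lower, with a median of -0.13 (camera adjusted p = 5.05e-04; adjusted p = 0.711 with an estimated correlation). Of these, 1 passed over the list alone and 9 with the replicate block. The phosphofructokinase Pfkp was at -0.33 (SE 0.0777) and the aldolase Aldoa at -0.24 (SE 0.0691), with edgeR adjusted p of 0.196 and 0.27 (5.11e-08 and 5.72e-06 with the replicate block). Without control siRNA replicate 1 or without Lkb1 siRNA replicate 2 this list did not pass (camera adjusted p = 0.171 and 0.202). Of 36 nuclear genes of the mitochondrial respiratory chain 33 were lower, with a median of -0.09 (camera adjusted p = 8.54e-05; adjusted p = 0.767 with an estimated correlation). None passed over all genes or over the list alone, and 8 passed with the replicate block. Uqcrc1 and Ndufa2 were both at -0.19, with SE 0.0697 and 0.0695 and an edgeR adjusted p of 0.358 each (0.00145 and 0.019 with the block). The median was -0.06 both without control siRNA replicate 1, where the call was lost (camera adjusted p = 0.0573), and without Lkb1 siRNA replicate 2. The call was also lost when the trend with gene length was removed, with a median of -0.043 (camera adjusted p = 0.117, or 0.0839 with the replicate block). Of the 19 pyruvate and alanine metabolism genes 13 were lower, and the list did not pass (camera adjusted p = 0.162). Its members with the smallest p were Gpt2, an alanine aminotransferase, and Pdk1, a pyruvate dehydrogenase kinase. Their log2 fold changes were -0.30 (SE 0.0819) and -0.15 (SE 0.0686), with edgeR adjusted p of 0.253 and 0.452 (2.82e-07 and 0.0293 with the block). Without control siRNA replicate 2 or without Lkb1 siRNA replicate 1 this list passed as lower (camera adjusted p = 0.0301 and 0.0247).

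All 40 cytosolic ribosomal protein genes were lower, 39 of them in both batches, with a median of -0.13 (camera adjusted p = 1.1e-11; adjusted p = 0.47 with an estimated correlation). None passed over all genes, 1 over the list alone and 23 with the replicate block. Rpl38 stood apart at 116.3 ± 1.05 against 69.5 ± 13.8 CPM (log2 fold change -0.74, SE 0.114, edgeR adjusted p = 0.073; 2.43e-37 with the replicate block), and Rps15 was at -0.28 (SE 0.0898; edgeR adjusted p = 0.321, and 4.99e-08 with the block). Short genes were lower than long genes in general: the median log2 fold change was -0.07 in the tenth of genes with the shortest transcripts and 0.04 in the tenth with the longest. With this trend removed in the blocked fit, the median of the ribosomal protein genes was -0.07 (camera adjusted p = 1.44e-05; adjusted p = 0.653 with an estimated correlation).

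The lists of mesenchymal and smooth muscle genes fell. Of 19 mesenchymal and fibroblast genes 17 were lower, with a median of -0.13 (camera adjusted p = 2.25e-05; adjusted p = 0.767 with an estimated correlation). Of these, 2 passed over the list alone and 10 with the replicate block. The intermediate filament gene Vim was at -0.33 (SE 0.0579), the fibrillin Fbn1 at -0.27 (SE 0.0704) and the collagen chain Col1a1 at -0.35 (SE 0.112), with edgeR adjusted p of 0.0908, 0.227 and 0.319 (1.03e-13, 2.36e-06 and 1.36e-14 with the replicate block). The list did not pass without Lkb1 siRNA replicate 1 (camera adjusted p = 0.104), and its median was -0.067 without control siRNA replicate 2 and -0.246 without Lkb1 siRNA replicate 2. Of 15 smooth muscle and myofibroblast genes 12 were lower, with a median of -0.09 (camera adjusted p = 0.0044; adjusted p = 0.632 with an estimated correlation). Of these, 2 passed over the list alone and 6 with the replicate block. Acta2, smooth muscle actin, was at -0.41 (SE 0.0709) and Tagln at -0.305 (SE 0.0792), with edgeR adjusted p of 0.0908 and 0.227 (1.59e-14 and 4.99e-08 with the block). This list did not pass without control siRNA replicate 2 (median -0.055, camera adjusted p = 0.0759) or without Lkb1 siRNA replicate 1 (0.0972).

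The remaining lower lists concerned stress and degradation. Of 26 interferon response genes 24 were lower, with a median of -0.215 (camera adjusted p = 1.15e-04; adjusted p = 0.894 with an estimated correlation). None passed over all genes or over the list alone, and 7 passed with the replicate block. Isg15 was at 18.3 ± 0.915 against 13.8 ± 2.44 CPM and Bst2 at 13.2 ± 3.88 against 8.81 ± 1.03 CPM, both with an edgeR adjusted p of 0.344 (0.00137 and 5.58e-05 with the block). The size of this shift rested on single libraries: the list did not pass without control siRNA replicate 2 (median -0.032, camera adjusted p = 0.497) or without Lkb1 siRNA replicate 1 (median -0.073, 0.17), and its median was -0.366 without control siRNA replicate 1 and -0.46 without Lkb1 siRNA replicate 2. Of 21 unfolded protein response genes 18 were lower, with a median of -0.12 (camera adjusted p = 5.05e-04; adjusted p = 0.711 with an estimated correlation), none passed without the block and 8 as lower and 1 as higher with it. The sensor Atf6 was at -0.30 (SE 0.0777) and the disulfide isomerase Pdia6 at -0.22 (SE 0.0718), with edgeR adjusted p of 0.227 and 0.33 (2.28e-04 and 2.09e-04 with the block). This call was lost without control siRNA replicate 1 (median -0.054, camera adjusted p = 0.0945). Of 34 lysosome and autophagy genes 26 were lower, with a median of -0.09 (camera adjusted p = 0.00305, and 0.711 with an estimated correlation). None passed over all genes or over the list alone, and 9 passed with the replicate block. The protease Ctsl was at -0.23 (SE 0.0625) and Gabarapl1 at -0.21 (SE 0.0647), with edgeR adjusted p of 0.258 and 0.311 (3.31e-05 and 6.22e-04 with the block). The list median was -0.064 without control siRNA replicate 2 and -0.062 without Lkb1 siRNA replicate 1, and the list did not pass in either fit.

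**Figure D2:**
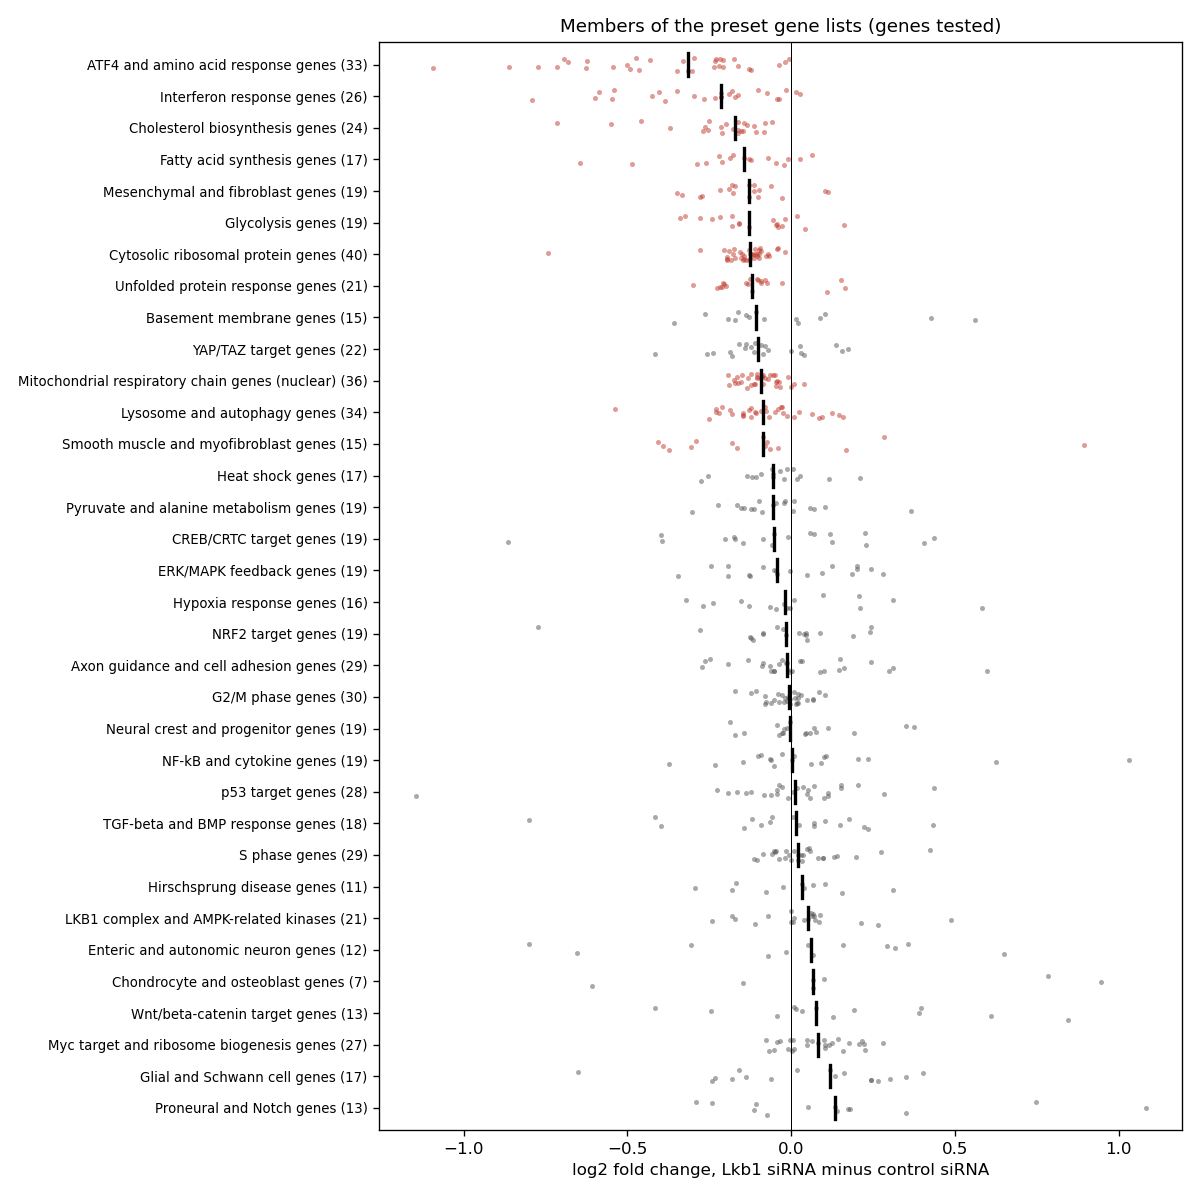
The log2 fold change (Lkb1 siRNA minus control siRNA, horizontal axis) of each tested member of the 34 lists, with the number of tested members after each name; each point is a gene, black bars are list medians, and red marks lists with a camera adjusted p under 0.05. The 33 ATF4 and amino acid response genes all lie below 0, with a median of -0.315, while the 19 neural crest and progenitor genes lie on both sides of a median of -0.005.

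With the replicate block, 3 further lists passed. In the main test, to which the SE belong, none of their members passed over all genes. Of 27 Myc target and ribosome biogenesis genes 20 were higher, with a median of 0.08 (camera adjusted p = 0.0754 without and 5.11e-04 with the block; adjusted p = 0.955 with an estimated correlation in the blocked fit). Nop56, a nucleolar protein, was at 0.22 (SE 0.118) and the RNA polymerase I subunit Polr1b at 0.225 (SE 0.123), with edgeR adjusted p of 9.22e-05 and 9.38e-04 with the block. The direction of this list turned on single libraries: it passed as higher without control siRNA replicate 1 (camera adjusted p = 1.9e-15) or without Lkb1 siRNA replicate 2 (4.41e-07), and as lower without control siRNA replicate 2 (0.0125). Without the block it also passed as higher with library size in place of TMM (0.0489) and with the length trend removed (0.0314). Of 15 basement membrane genes 9 were lower (camera adjusted p = 0.0811 without and 0.0218 with the block; adjusted p = 0.664 with an estimated correlation in the blocked fit), with the laminin chain Lama5 at -0.36 (SE 0.0817) and Col4a2 at -0.19 (SE 0.0632), with edgeR adjusted p of 2.42e-09 and 7.15e-04 with the block. Col15a1 went the other way, with a log2 fold change of 0.561 (SE 0.212; edgeR adjusted p = 0.375, and 0.0235 with the block), and with the block 1 member passed as higher and 6 as lower. This list also passed without control siRNA replicate 1 (camera adjusted p = 0.0259) and without Lkb1 siRNA replicate 2 (0.00236), and, without the block, with at least 1 count in any library (0.0258), with a minimum of 5 CPM (0.00928) and with the length trend removed (0.00635). Of 22 YAP/TAZ target genes 15 were lower (camera adjusted p = 0.0811 without and 0.0426 with the block; adjusted p = 0.659 with an estimated correlation in the blocked fit), with Amotl2 at -0.26 (SE 0.0834) and the receptor kinase Axl at -0.19 (SE 0.0624), with edgeR adjusted p of 1e-05 and 0.00131 with the block. The next members by p were higher, Ajuba at 0.174 (SE 0.0731) and Ptpn14 at 0.154 (SE 0.0688) (edgeR adjusted p with the block 0.0212 and 0.0404), and with the block 3 members passed as higher and 4 as lower. Without the block this list passed with the length trend removed (camera adjusted p = 0.0185).

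The lists of neural crest identity and fate did not pass with or without the block. Of 19 neural crest and progenitor genes 9 were higher and 10 lower (camera adjusted p = 0.785). Cdh6 was at 0.37 (SE 0.145) and the crest transcription factor Snai2 at -0.17 (SE 0.0857). Of 17 glial and Schwann cell genes 10 were higher and 7 lower (camera adjusted p = 0.935), with 1 gene passing as lower adjusted over the list alone. The neuregulin receptor gene Erbb3, needed for Schwann cell precursors, was at 12.7 ± 1.08 against 8.10 ± 0.0623 CPM (log2 fold change -0.65, SE 0.136, edgeR adjusted p = 0.139 and 7.27e-06 with the replicate block), and Gpm6b was at 34.4 ± 1.57 against 42.4 ± 2.29 CPM (edgeR adjusted p = 0.27 and 5.53e-04 with the block). Of 12 enteric and autonomic neuron genes 7 were higher (camera adjusted p = 0.935), with the neurturin receptor Gfra2 at -0.80 (SE 0.25), Bnc2 at -0.305 (SE 0.101), Map2 at 0.356 (SE 0.148) and Tubb3 at 0.317 (SE 0.167). Of 11 Hirschsprung disease genes 6 were higher (camera adjusted p = 0.919), with Sema3d at 0.31 (SE 0.15). Of 13 proneural and Notch genes 8 were higher (camera adjusted p = 0.202), 2 of them passing adjusted over the list alone and 1 gene as lower. The Notch ligand Dll1 was at 1.57 ± 0.056 against 3.33 ± 0.275 CPM, Dtx4 was at -0.29 (SE 0.0683) and Jag2 at 0.351 (SE 0.0933). In the main test, to which the SE belong, none of the members named here passed, with edgeR adjusted p from 0.139 (Erbb3) to 0.515 (Tubb3). With the replicate block, the members named here had edgeR adjusted p from 3.97e-08 (Jag2) to 0.0436 (Tubb3). DESeq2 with the block passed Jag2 (adjusted p = 0.0494) and none of the others, with adjusted p from 0.0749 (Sema3d) to 0.655 (Snai2) where it gave one. Median, mean and test differed in sign for the neural crest genes (median -0.005, mean 0.034, tested as higher), the Hirschsprung disease genes (median 0.033, mean -0.003, tested as higher) and the enteric neuron genes (median 0.06, mean 0.004, tested as lower).

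Lists of LKB1 signalling, p53 targets, the S phase, Wnt targets, cartilage and bone, and cytokines did not pass either. Of 21 genes of the LKB1 complex and AMPK-related kinases, Stk11 not among them, 16 were higher (camera adjusted p = 0.803) and none passed. In both batches, 7 of the 21 were higher and 5 lower. Sik2 was at -0.24 (SE 0.0876), the AMPK catalytic subunit Prkaa1 at -0.18 (SE 0.0669), and the regulatory subunit Prkab1 at 0.212 (SE 0.0947). Of 19 CREB/CRTC target genes 8 were higher (camera adjusted p = 0.919), with Nr4a1 at 0.44 (SE 0.142), Fosb at 0.41 (SE 0.136) and Inhba at -0.398 (SE 0.156). Of 28 p53 target genes 15 were higher and 13 lower (camera adjusted p = 0.935; median 0.012, mean -0.016, tested as lower). The junction protein gene Perp was at 6.96 ± 1.42 against 3.14 ± 0.0108 CPM (edgeR adjusted p = 0.106) and Phlda3 at 0.20 (SE 0.0796). Of 29 S phase genes 18 were higher (camera adjusted p = 0.26), with the cyclins Ccne2 at 0.42 (SE 0.101) and Ccne1 at 0.275 (SE 0.0974). Of 13 Wnt/beta-catenin target genes 10 were higher (camera adjusted p = 0.228), with Bmp4 at -0.415 (SE 0.103) and Lgr5 at 0.395 (SE 0.113). Of 7 chondrocyte and osteoblast genes 5 were higher (camera adjusted p = 0.785), with the proteoglycan Acan at -0.61 (SE 0.0863) and Col11a2 at 0.945 (SE 0.205). Of 19 NF-kB and cytokine genes 10 were higher (camera adjusted p = 0.803), with the chemokines Cxcl1 at 0.63 (SE 0.147) and Cxcl5 at 1.03 (SE 0.302), Tnfaip2 at -0.231 (SE 0.0862) and Cxcl12 at -0.372 (SE 0.158). With the replicate block, the members named here had edgeR adjusted p from 3.83e-27 (Cxcl1) to 0.0238 (Inhba). DESeq2 with the block gave an adjusted p of 1.42e-04 for Acan. It did not pass Prkaa1 (0.588), Prkab1 (0.695), Phlda3 (0.628) or Fosb (0.789), and gave no adjusted p for Sik2, Nr4a1, Inhba, Perp and Col11a2. None of these lists had a member passing over all genes. Adjusted over the list alone, 2 chondrocyte genes passed as higher and 1 as lower, and at most 1 gene in either direction passed in each of the others. The S phase list passed as higher without control siRNA replicate 1 (camera adjusted p = 1.72e-04) or without Lkb1 siRNA replicate 2 (0.0029), and the Wnt list without Lkb1 siRNA replicate 1 (0.0247).

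The other 7 lists, on the G2/M phase, heat shock, NRF2, hypoxia, TGF-beta and BMP, ERK/MAPK feedback and axon guidance, had camera adjusted p from 0.337 to 0.919. The ERK/MAPK feedback genes passed in opposite directions with different libraries left out, as higher without control siRNA replicate 1 (camera adjusted p = 0.03) and as lower without control siRNA replicate 2 (0.00827) or without Lkb1 siRNA replicate 1 (0.0247), and the heat shock genes passed as lower without control siRNA replicate 2 (0.0248). A further 4 lists had too few tested members, among them melanocyte genes (3 tested) and macrophage and blood vessel genes (1 tested).

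At the transcript level, 34279 transcripts were tested with edgeR and none passed, with or without the replicate block, while 1074 were higher and 1239 lower at an unadjusted p under 0.05. No other tool was run on them. One transcript held 95.7% of the Stk11 counts. Its counts were 2122 and 2178 in the control siRNA libraries and 1392 and 1452 in the Lkb1 siRNA libraries, a log2 fold change of -0.56 (SE 0.0526, edgeR adjusted p = 0.687). The main Trp53 transcript had 464 and 489 counts against 754 and 765, a log2 fold change of 0.71 (SE 0.0799, edgeR adjusted p = 0.687).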

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

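The length corrections, limma-voom, the non-robust blocked fit, the blocked fit with a fold-change threshold and the blocked estimated correlation were chosen after the data were seen; the other alternatives were fixed before. No gene named by the rule and none of the 11 called lists turned direction. The genes named outside the rule were not recomputed in all of the alternatives. Among them Cdkn1a had a log2 fold change of -0.288 in batch 1 and 0.297 in batch 2. Among called genes other than Stk11, 128 of 159 recomputed values stayed past the threshold and 31 lost it, 6 each with library size only and with at least 5 CPM in 2 libraries, 9 with each limma fit on FPKM and 1 with the length correction. These values leave out the fold-change threshold of 1.2, under which none of these genes passed without the block. They also leave out Trib3, Rsc1a1 and Stbd1 in DESeq2 with the block, where these genes received no adjusted p. Among called lists, 130 of 176 values held and 46 did not, 11 of them each with the estimated correlation, with fry and with the estimated correlation in the blocked fit. The cause was not tested unless given.

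With the replicate block 806 genes were higher and 854 lower, with 10 of the 10 main calls shared, and 1 list was higher. The lower residual spread of that fit (3.15 against 6.39%) and its infinite median of prior degrees of freedom (against 7.27) go with the larger counts. Blocked fits with a length correction gave 725 and 813 genes and 1 list higher, of which 1373 genes were shared with the plain block; without robust estimation 798 and 857 and 1 list higher; limma-voom with the block 805 and 851; and a fold-change threshold of 1.2 left 40 and 55, or 0 and 0 without the block. DESeq2 called 16 and 31 genes without the block and 44 and 80 with it. With the block it gave no adjusted p to some genes that edgeR tested, Erbb3 and Sik2 among them. Its counts are therefore not over the same genes as those of edgeR. With the block DESeq2 shared 7 of the 10 main calls, as Trib3, Rsc1a1 and Stbd1 received no adjusted p. Among named genes not called in the main test, 65 passed with the edgeR block and 19 with DESeq2 and the block, which gave some no adjusted p. The counts were 2 and 1 with library size only, where 1 list was higher; 13 and 32 with at least 1 count in any library; 2 and 1 with at least 5 CPM in 2 libraries; and 0 and 0 with either limma fit on FPKM. The length correction without the block gave 1 list higher. The estimated correlation and fry gave 0 lists lower, as did the estimated correlation with the block. A planted shift of -0.3 was missed by both tests in simulated data, but with independent genes, so this does not show the lost calls to be sound. Apart from the counts and the genes and lists given with it, the replicate block changed no other call.

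Leaving out 1 library gave from 24 to 136 higher genes, from 42 to 143 lower genes and from 0 to 3 higher lists; the lone library is then assumed to vary like the other group. The lists of ATF4, cholesterol, fatty acid and ribosomal protein genes passed as lower in each of these 4 fits. The Stk11 log2 fold change lost its threshold at -0.518 with library size only, -0.548 with at least 5 CPM in 2 libraries, and -0.505 and -0.516 with limma on FPKM; its adjusted p ran from 1.28e-22 to 0.122 over the alternatives other than the fold-change threshold of 1.2, which was run for counts only and without the block called neither Stk11 nor any other gene. With 2 libraries per group and 17426719 to 19324675 counts each, 28 of 50 simulated 1.5-fold changes and 41 of 50 simulated 2-fold changes were found by the main test with batch differences, so changes of these sizes can be missed.

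Of 368 values of the lists not called, 49 were tested in the opposite direction, and 2 of these passed: the ERK/MAPK feedback list as higher without control siRNA replicate 1 (median log2 fold change 0.164, camera adjusted p = 0.03) and the Myc list as lower without control siRNA replicate 2 (-0.076, 0.0125). The others did not pass on either side, and the test follows the whole list, so a median can keep its sign. The list medians in these fits were -0.053 (CREB/CRTC), 0.064 (enteric neuron) and 0.012 (p53) with the replicate block, with or without robust estimation or the estimated correlation, and 0.027 (glial), 0.061 (enteric neuron) and -0.02 (axon guidance) with at least 1 count in any library. They were -0.049 (CREB/CRTC), 0.023 (glial) and 0.297 (enteric neuron) with at least 5 CPM in 2 libraries, and 0.06 (enteric neuron) and 0.012 (p53) with cameraPR. They were 0.101 (glial), 0.01 (Hirschsprung) and -0.03 (axon guidance) with the length correction, and -0.029 (CREB/CRTC), 0.013 (p53), 0.004 (NRF2) and -0.03 (axon guidance) with the replicate block and length correction. With each library left out in turn, the medians ran from -0.01 to 0.094 (neural crest), -0.046 to 0.188 (glial), 0.044 to 0.065 (enteric neuron), -0.075 to 0.061 (NRF2), -0.179 to 0.164 (ERK/MAPK), -0.045 to 0.091 (NF-kB), -0.125 to 0.015 (heat shock), -0.087 to 0.015 (CREB/CRTC). For the other lists that turned they ran from -0.038 to 0.016 (p53), -0.062 to 0.13 (S phase), -0.116 to 0.095 (TGF-beta and BMP), -0.076 to 0.238 (Myc), 0.011 to 0.034 (LKB1 kinase), -0.072 to 0.045 (Hirschsprung), -0.038 to 0.024 (G2/M phase), -0.002 to 0.008 (axon guidance).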

Other observations

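All family tests and technical tests in this part were chosen after the results were seen. A total of 19 gene families defined by symbol were tested with camera. The SR splicing factor genes were higher in 9 of 10 members (median log2 fold change 0.25; camera adjusted p = 1.32e-08; adjusted p = 0.918 with an estimated correlation), 8 of them passing with the replicate block. Srsf6 went from 229.8 ± 10.0 to 302.5 ± 3.28 CPM (edgeR adjusted p = 0.0847 without and 7.91e-14 with the block) and Srsf11 from 156.7 ± 5.94 to 206.1 ± 3.06 CPM (0.0847 and 1.41e-13). The Ddx helicase genes (28 of 35 higher, camera adjusted p = 0.0346) and the Zfp zinc finger genes (242 of 343 higher, 0.0189) also passed. With an estimated correlation both had a camera adjusted p of 0.918. In both batches, 20 Ddx genes were higher and 4 lower, and 152 Zfp genes were higher and 62 lower. In the blocked fit with the length trend removed, the latter had a median of 0.042, against 0.055 before, and did not pass (0.0736). The other families of splicing genes tested did not pass: the hnRNP genes were higher in 10 and lower in 10 of 20 members (camera adjusted p = 0.784), and the snRNP and Lsm genes were higher in 8 and lower in 17 of 25 (median -0.038, camera adjusted p = 0.395). The collagen chain genes did not pass either, with 19 of 32 higher (median 0.086, camera adjusted p = 0.517) and, with the replicate block, 5 passing as higher and 9 as lower.

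The aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, were lower in 16 of 17 members (median -0.16; camera adjusted p = 1.08e-04; adjusted p = 0.918 with an estimated correlation), 10 of them passing with the replicate block. None of the 17 was in the ATF4 list. Sars went from 339.1 ± 22.7 to 259.6 ± 18.3 CPM (edgeR adjusted p = 0.134 without and 5.17e-13 with the block). Aars, Gars and Nars had log2 fold changes of -0.25, -0.235 and -0.24. In all, 15927 words of 7 bases were searched in the 3′ UTRs of 11743 genes. Large log2 fold changes were first clipped, and all were adjusted for 3′ UTR length, GC content and expression. Words were ranked by a z score. GGACAAA had the lowest, at -4.89, and 2 of 100 shuffles gave a word as low. Its 1369 genes differed from the rest by a mean adjusted log2 fold change of -0.0277. GTTTTGT had the highest z score, 4.45, with 6 of 100 shuffles as high, and a mean adjusted difference of 0.0163 over 3569 genes. The Trp53 3′ UTR held 1 or more of the 3 highest words but not that one. These words were found in 3569, 3411 and 4790 genes, so they are common. Penk, which encodes enkephalin, had 90.0 ± 11.1 against 146.6 ± 26.7 CPM (edgeR adjusted p = 0.0908 without and 1.26e-38 with the block).

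The fall of the ATF4 and amino acid response genes was not a matter of 1 batch, since 30 of 33 members were lower in both batches. It was not the length trend alone: with the trend removed in the blocked fit the median was -0.325, against -0.314 before, and 10000 random lists matched on length and expression gave medians no lower than -0.116. A seed match of an siRNA stays open, because the siRNA sequences were not given in the sources used here. The word whose genes were lowest was found in 4 of the 33 members and in 11.7% of all genes. Of the 33, 12 held any of the 3 lowest words, which were found in 1369, 1850 and 2551 of the 11743 genes searched. The share of all genes with any of the 3 was not computed, so the 12 cannot be read as an excess. Lower LKB1 and other effects of the siRNA pool stay open as well, which a single pool cannot separate. Atf4 itself was at 311.2 ± 15.0 against 269.5 ± 26.3 CPM (edgeR adjusted p = 0.392 without and 4.15e-04 with the block).

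The lower level of cytosolic ribosomal protein genes may come in part from the trend with gene length, as these genes are short. Of 10000 random lists matched on length and expression, the median was -0.091 in the blocked fit and the lowest -0.144, against -0.127 for the list, which lay at percentile 0.32 of them. The removal of the trend argues against length as the whole cause. After the correction the list stayed at a median of -0.073, with 37 of 40 members lower. An SE of 0.0078 for that median was taken from the spread among members, which are not independent replicates. It is therefore no error of the siRNA effect, and the camera adjusted p was 0.653 with an estimated correlation. A batch difference is argued against by 39 of 40 members lower in both batches. The source of the length trend was not tested, and it was present in both batches, with a correlation across genes between length and log2 fold change of 0.137 and 0.163 (Spearman's rho; genes are not independent replicates). No explanation in terms of LKB1 was tested beyond the comparison of the groups.

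Trp53 rose while the list of its targets did not pass. Reads of the neighbouring gene Wrap53 do not account for it: Wrap53 was at a log2 fold change of 0.126 (SE 0.109) in the blocked fit against 0.736 (SE 0.07) for Trp53, and the length correction left Trp53 at 0.76. Whether p53 activity changed stays open: the target list had a camera adjusted p of 0.939 with the block, with 2 members passing as higher and 2 as lower, and Cdkn1a and Mdm2 were at log2 fold changes of 0.02 (SE 0.183) and 0.11 (SE 0.0741). It likewise stays open whether the non-targeting pool lowers Trp53 or the Lkb1 pool raises it, as no untransfected library was analysed here. p53 protein was not analysed here.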
